A study of Drosophila melanogaster with 2 samples.

How the data were processed

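Chromatin immunoprecipitation sequencing was done by the authors on whole Drosophila embryos of 0 to 24 hours that express Psq with a C-terminal GFP, precipitated with an anti-GFP antibody. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp, and the 2 samples are biological replicates numbered 3 and 4. The labels name a control experiment, which was not analysed here. All samples belong to 1 group, so no comparison between groups was made.

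Per the text files deposited with the samples, the authors called a relaxed list of peaks and background on the alignment of each replicate against a control alignment, and another on both replicates pooled. They then derived an optimal IDR-thresholded list from the replicates' lists and the pooled list. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited score of each peak, in the seventh column, is the caller's own statistic. It has its own scale in each list, so it was used to rank, filter and describe peaks within a list. The deposited −log10 q of each peak is capped at a maximum per list. All 2999 IDR peaks were at that maximum, 3.87, so q could not rank them. The summit position was taken from the deposited offset in the last column, and a summit given at the end of its peak was kept inside it. Every list exists for the assemblies dm6 and dm3, per the labels. Coordinates are dm6, written 1-based. The dm3 lists were used for peak numbers and replicate overlap.

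The 2999 IDR peaks of dm6 were the same intervals and summits as 2999 peaks of the pooled list, and were all of the pooled peaks with a score at or above the lowest IDR score, 72.5. Among them, 34 peaks repeat an interval of another peak with a different summit. Each relaxed list had 30000 peaks. The files hold no read numbers, so the depth of each library is unknown and no precision can be drawn from it. Most pooled peaks have the same width: 97.8% were 440 bp.

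Gene models came from Ensembl release 115 for the same assembly, with transposable elements left out. Chromosome sequence came from the RefSeq dm6 assembly, limited to arms 2L, 2R, 3L, 3R, 4 and X, and all dm6 peaks lay on them. A promoter summit was within 500 bp of any annotated TSS. Other summits were classed in the order coding exon, 5' UTR, 3' UTR, other exon, intron and intergenic. Expected shares came from shifting all summits of an arm by the same random distance around that arm, 1000 times for promoters and 100 times for all classes. A gene was called bound when an IDR summit was within 1000 bp of any of its TSSs, and 13945 protein-coding genes were the background. The 22 gene lists, 11 motifs, tests and alternatives were fixed before the data were examined, except those named as chosen after seeing the data. Motif tests by peak class and among the 500 strongest peaks were also outside this plan. So were the shares among the 600 highest-scoring and 599 lowest-scoring peaks. The names h, Dl, calypso, nos, cappu, Hsp67Bb and dec-1 matched no protein-coding gene of that exact name in the annotation and were not analysed here.

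Motifs were searched as exact patterns on both strands within 100 bp of the summit and in 2 flank windows centred 1000 bp away. Named genes were those with the nearest TSS to the 20 strongest IDR peaks found in both replicate lists, up to 3 bound members of each list with the highest scores, and psq and Trl. Other genes near a named summit were named after its values were seen. Score differences were tested by permutation with 100000 resamples, and p-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Replicate agreement used an overlap of at least 1 bp. With 2 replicates, no test between replicates was possible.

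Alternatives were dm3 in place of dm6, other overlap rules, the 1499 highest-scoring IDR peaks, the 2999 strongest peaks of either replicate alone, TSS windows of 250 and 1000 bp for promoters, and of 500 and 2000 bp for genes. Motif windows of 50 and 250 bp, flanks at 2000 bp, the gene body, 1 TSS per gene and 10000 random lists matched on the number of TSSs were also tried. Alternatives added after seeing the data were protein-coding TSSs only, shifts of 10000 to 50000 bp, protein-coding genes as the measure of arm size, promoters of unbound genes as motif background, and the gene with the nearest TSS.

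The statistics were tested on simulated peak sets of 2999 summits on the real annotation. With summits placed at random, the promoter test made a call in 7 of 100 draws, the arm test called 1 arm and the list test 6 lists in all 100 draws. With 60% of summits placed at promoters, ribosomal protein genes drawn 5 times as often and GAGAG written into 20% of summits, the promoter share, the ribosomal protein list and the GAGAG motif were called in 100 of 100 draws. The planted score difference was called in 96. In those draws calls that were not planted numbered 45 for arms, 24 for lists and 454 for motifs other than GAGAG and GAGAGAG, including CA repeats in 23 draws. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.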

Results

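Binding of the Drosophila melanogaster protein Psq was mapped by chromatin immunoprecipitation followed by sequencing in whole embryos collected from 0 to 24 hours, with males and females pooled. Psq (pipsqueak) is a BTB-domain DNA-binding protein known to bind GAGA-type repeats. The flies carried a transgene that expresses Psq with GFP at its C terminus, and the precipitation used an antibody to GFP. There was 1 group of 2 biological replicates, which the labels number 3 and 4, and no second condition. The measurement therefore shows where tagged Psq was found in embryos and how well the replicates repeated each other, and holds no contrast between conditions. Each replicate had its own list of 30000 peaks, a length that includes background. Read numbers are not in these lists, so the depth of each library is unknown. The 95% intervals of shares given here are Wilson intervals and cover counting error only.

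The set that passed the authors' test of irreproducible discovery rate (IDR) held 2999 peaks on the dm6 assembly. The highest score, 2011, lay on arm 3L from 14002628 to 14003393, in an intron of upSET (FBgn0036398), which encodes a SET-domain chromatin protein. Its summit was 816 bp downstream of the nearest transcription start site (TSS). The next strongest peak, with a score of 1809, lay on 2R from 10558558 to 10559271, in an intron of psq itself (FBgn0263102). The third was at CG1910, with a score of 1295 and a summit 122 bp upstream of a TSS on 3R (31748038 to 31748707). A peak at gpp, which encodes the histone H3 lysine 79 methyltransferase, followed with a score of 1115, on 3R from 6406524 to 6407068 and 52 bp upstream of a TSS. The fifth was a coding exon summit in Uba1, which encodes the ubiquitin-activating enzyme, on 2R from 9692558 to 9693145 with a score of 1091. Peak scores are the authors' own and rank peaks within a list.

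Of the 20 strongest peaks found in both replicate lists, 10 had their summit within 500 bp of a TSS, 8 lay in introns, 1 in a coding exon and 1 between genes. They belonged to 19 nearest genes, because MEP-1, which encodes a zinc-finger protein of a Mi-2 complex, had 2 of them, with scores of 999 and 799.5. Other regulators of transcription and chromatin in this group were Hel89B (982), cbt (901) and REPTOR (839.8). The RNA-binding protein genes Rbfox1 (829.7) and pum (809) were also there, the pum summit in an intron 6218 bp from the nearest TSS. FBXO11 (889), DnaJ-H (862), Pepck2 (839.4), tay (1064), CG14100 (880.4), CG32772 (803) and the non-coding gene lncRNA:CR44417 (956) made up the rest, with CG13323 (808), whose TSS was 11915 bp from an intergenic summit. For the lncRNA:CR44417 peak the nearest protein-coding TSS was that of Mapmodulin, at 2171 bp.

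The psq gene was among the most densely occupied loci. Within its 59.4 kb on 2R (10557888 to 10617280, plus strand), 19 IDR summits were found, 4 within 500 bp of an annotated TSS and 15 in introns. They lay in 17 distinct intervals. Some neighbouring summits, such as those at 10559675 and 10559878, had the same strongest overlapping peak in each replicate, so separate sites are fewer than summits. The intronic peak of score 1809 was 1076 bp downstream of the first TSS. Its score in the replicates' own lists was 786 in replicate 3 and 1033 in replicate 4, the second highest in each. Just outside the gene, a summit 90 bp upstream of the same TSS had a score of 380 (10557566 to 10557959). Further summits lay beside the internal TSSs, including 1 at 10569000 (score 175) and 1 at 10583741 (score 125). Trl, which encodes the GAGA factor, had 3 IDR summits within its 13.1 kb on 3L (14747929 to 14761049, minus strand). The strongest, with a score of 518 and rank 65, was intronic (14759331 to 14759685). The other 2 had scores of 150 and 101, and the one of 150 lay 103 bp downstream of a TSS.

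**Figure D1:**
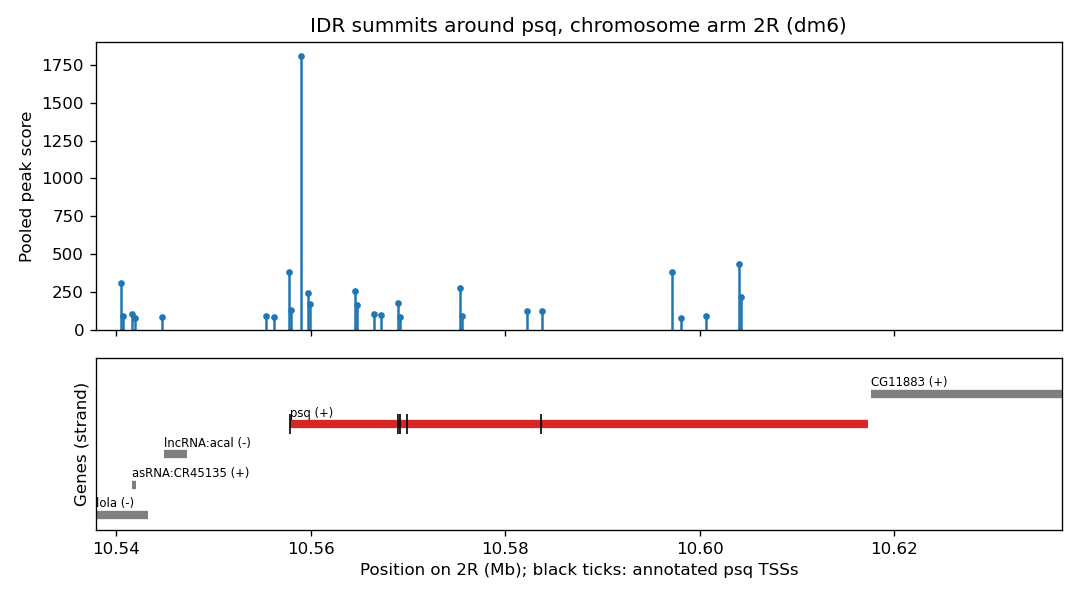
IDR summits around psq on 2R in dm6 coordinates (Mb), each drawn as a line whose height is the pooled peak score, above the annotated genes with psq in red and its TSSs as black ticks. The summit of score 1809 stands 1076 bp inside the gene, and 19 summits fall within psq.

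The replicates placed their strongest peaks at largely shared sites. Of the 2999 IDR peaks, 87.2% (85.9 to 88.3%) were overlapped by at least 1 bp by the 2999 strongest peaks of replicate 3 and 87.5% (86.3 to 88.7%) by those of replicate 4. The strongest peaks of both overlapped 2271 of them. Compared directly, 2297 of the 2999 strongest peaks of replicate 3 overlapped the strongest of replicate 4, or 76.6%. Shifting the replicate 3 peaks along their arms left an overlap of 1.76% on average, and at most 2.13% in 20 shifts. Across the 2994 IDR peaks found in both 30000-peak lists, the scores of the replicates had a Spearman correlation of 0.735 (bootstrap 95% interval 0.714 to 0.755). This correlation is across peaks, which are not independent replicates. The IDR peaks were the highest-scoring peaks of the list called on both replicates pooled. Their overlap with each replicate's strongest peaks was therefore partly built in. The median distance between the replicates' summits was 31 bp.

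**Figure D2:**
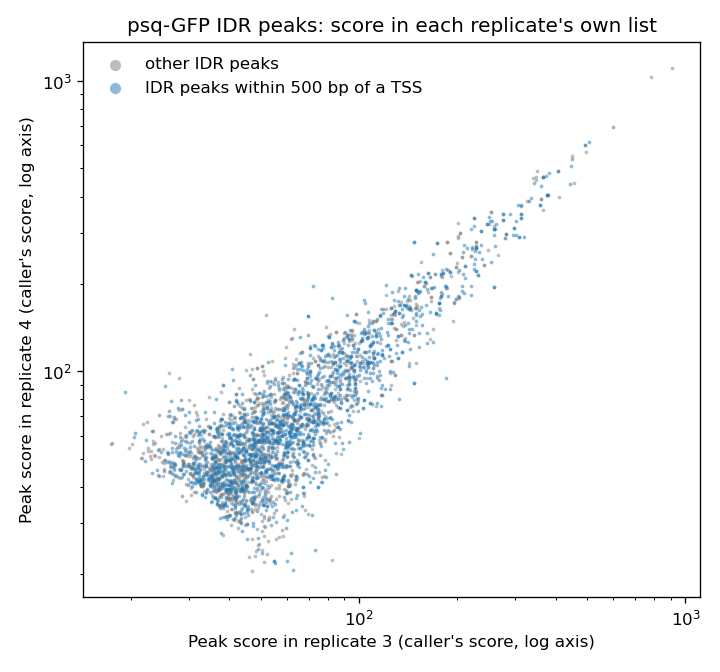
Score of each IDR peak in the list of replicate 3 (x axis) and replicate 4 (y axis), both on log axes, with peaks within 500 bp of a TSS in blue and others in grey. Points rise together with a Spearman correlation of 0.735 across 2994 peaks and scatter most at low scores.

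Psq-GFP summits were concentrated at promoters. Of the 2999 IDR summits, 1672 were within 500 bp of an annotated TSS, or 55.8% (54.0 to 57.5%). The same summits shifted along their arms gave 13.6% on average, a 4.10-fold difference, and at most 16.4% in 1000 shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Most promoter summits, 74.7%, lay on the upstream side of the nearest TSS. Introns held another 955 summits (31.8%) against 39.5% of shifted ones. Intergenic positions held 275 (9.17%) against 27.3%. A total of 328 summits lay more than 5000 bp from any TSS.

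Coding exons away from promoters were almost free of summits. They held 7 of 2999, or 0.233% (0.113 to 0.481%), while 13.8% of the shifted summits fell there and never under 10.2% in 100 shifts (one-sided permutation p = 0.01, the smallest that 100 shifts can give). The comparison of annotation classes was made after the files were seen. Besides Uba1, the 7 included summits within the genes otp (score 252), RhoGEF3 (175), Pde1c (152), CG10357 (84.1), bif (80.2) and CG7069 (79.9), all named after their values were seen. The 3' UTRs held 17 summits (0.567%) against 4.43% of shifted ones. The 5' UTRs beyond promoters held 37 (1.23%) against 0.610%.

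The large chromosome arms carried similar densities of peaks. Arms 2L, 2R, 3L, 3R and X had between 21.5 and 23.4 IDR peaks per Mb, and none differed from its share of sequence length (exact binomial test, two-sided, adjusted p from 0.471 to 0.981). Chromosome 4 had 9 peaks, or 6.68 per Mb, where its length would give 30.2 (0.298 of expectation, exact binomial test, adjusted p = 8.15e-05 over 6 arms). The 9 included a summit at the promoter of pan, which encodes the TCF protein of the Wnt pathway (70016 to 70455, score 95.9). Against its share of protein-coding genes, an alternative chosen after seeing the data, chromosome 4 was at 0.523 of expectation and did not pass (exact binomial test, adjusted p = 0.103), while 3L passed at 1.11 (adjusted p = 0.0168). Among the 1499 highest-scoring peaks chromosome 4 was at 0.397 of expectation by length and did not pass (exact binomial test, adjusted p = 0.0803). The binomial test takes peaks as independent draws, while peaks cluster, so its p-values can be too small.

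Among 13945 protein-coding genes, 2265 (16.2%, 15.6 to 16.9%) had an IDR summit within 1000 bp of a TSS. Of the 22 gene lists fixed in advance, 4 were bound more often than other genes and 2 less often at an adjusted p below 0.05 (Fisher's exact test, two-sided, adjusted over the 22 lists). The other 16 did not pass. Neighbouring genes can share a summit, so list members are not fully independent.

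In the trithorax and GAGA-associated list, 10 of 17 genes were bound (58.8%, 36.0 to 78.4%) against 16.2% of other genes (Fisher's exact test, adjusted p = 4.4e-04). The strongest were mor, psq and brm. The mor and brm genes encode subunits of the Brahma chromatin remodelling complex. The mor summit, 838 bp from its TSS with a score of 982, is the Hel89B peak, and the brm summit, 157 bp from a TSS, had a score of 303 (3L, 15982882 to 15983136) and lay nearer to Arl1, at 109 bp. Trl, trx, ash2, kis, skd, Bap60 and bab2 were the other bound members. Counting only the gene with the nearest TSS, chosen after seeing the data, left 7 bound members (Fisher's exact test, adjusted p = 0.00669).

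Polycomb group genes, which encode repressors of developmental genes, were bound at 9 of 17 members (52.9%, 31.0 to 73.8%, adjusted p = 0.00198 by Fisher's exact test). The strongest was ph-p, with a score of 492 on X (2137179 to 2137530), followed by Psc with 327 on 2R (12980078 to 12981197) and the histone H3 lysine 27 methyltransferase gene E(z) with 190 on 3L (10638022 to 10638135). The neighbouring genes ph-d and Su(z)2 were bound as well, with Su(z)12, Pcl, Sfmbt and Jarid2. Among the 1499 highest-scoring peaks the bound share of this list was 5.23 times that of other genes, compared with 3.27 times in the full set.

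Notch pathway genes were bound at 10 of 17 members (58.8%, 36.0 to 78.4%, adjusted p = 4.4e-04 by Fisher's exact test). The Notch inhibitor numb had the strongest summit, with a score of 232 at 247 bp from a TSS (2L, 9449440 to 9449692). E(spl)m3-HLH, a target repressor of the pathway, followed with 159 (3R, 26021199 to 26021638), and fng, which encodes a glycosyltransferase that modifies Notch, with 144 (3L, 20949305 to 20949744). The receptor gene N, the antagonist H, mam, mib1, neur, E(spl)m7-HLH and E(spl)mdelta-HLH were also bound.

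Genes of the cytosolic ribosome were the bound list with the most members. Of 92 ribosomal protein genes, 50 had a summit within 1000 bp of a TSS (54.3%, 44.2 to 64.1%) against 16.0% of other genes, a ratio of 3.40 (Fisher's exact test, adjusted p = 1.1e-15). The strongest were RpL7 with a score of 309 (2L, 10200900 to 10201144), RpS27 with 305 (3R, 25247414 to 25247668) and RpL23A with 293 (3L, 1668623 to 1668862), with summits 25, 28 and 74 bp from a TSS. Proteasome genes were taken by gene name, without a check that each member is used in all cells. Of these, 5 of 48 were bound (10.4%, 4.53 to 22.2%), and the list did not pass (Fisher's exact test, adjusted p = 0.534). Rpn6 (107), Rpn5 (107) and Rpn3 (92.4) had the highest scores among them, the Rpn6 and Rpn5 summits nearer to the TSSs of ave and Hat1. By nearest TSS 1 of 48 was bound, a share ratio to other genes of 0.180 in place of 0.641 (Fisher's exact test, adjusted p = 0.0946). Among the 1499 highest-scoring peaks 0 proteasome genes were bound, and the list passed as lower (Fisher's exact test, adjusted p = 0.0491).

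Chemoreceptor and cuticle protein genes were bound less often than other genes. Chemoreceptor genes, which encode odorant, gustatory and ionotropic receptors, had 2 of 179 members bound (1.12%, 0.307 to 3.98%, adjusted p = 1.49e-10 by Fisher's exact test). These were Or88a (133) and Gr32a (95.6), with summits 682 and 788 bp from their TSSs, and neither had the nearest TSS to its summit. The share ratio to other genes was 0.0680 and lay between 0 and 0.194 under the alternatives, with 0.104 and 0.105 when replicate 3 or replicate 4 was left out. Cuticle protein genes had 1 of 70 bound, Cpr73D (74.3), or 1.43% (0.253 to 7.66%, Fisher's exact test, adjusted p = 5.1e-04), and 0 when replicate 3 was left out. Chorion and vitelline membrane genes had 0 of 15, with an upper bound of 20.4%. Muscle structural genes had 1 of 18, sls (161), with a share ratio of 0.342 that was 0.696 without replicate 3, and neuronal function genes 1 of 17, Syx1A (559). None of these 3 lists passed the test, with adjusted p of 0.371, 0.534 and 0.534.

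The embryonic patterning and cell fate lists did not pass, nor did the heat shock and germ line lists, with adjusted p from 0.534 to 1 (Fisher's exact test). Homeotic genes had 1 of 8 members bound, Abd-B (97.7). Without replicate 4 the Abd-B peak was at rank 3644, outside the 2999 strongest, and the share ratio of the list was 0. The gap and head gap list, which also holds bcd and cad although they are not gap genes, had 3 of 14 bound. These were bcd (106), oc (91.0) and cad (90.8). Pair-rule genes had 0 of 7, which allows up to 35.4%. Segment polarity genes had 4 of 17, led by the Wnt antagonist nkd (139), mid (99.6) and pan (95.9), and dorsoventral genes 1 of 18, brk (82.1). Neural fate genes had 2 of 20, elav (328) and brat (207), and mesoderm genes 3 of 13, tin (124), htl (89.9) and how (75.5). Without replicate 4 the share ratio was 0.946 in place of 0.615 for neural fate genes and 0.971 in place of 1.42 for mesoderm genes. Eye determination genes had 2 of 9, eyg (148) and dac (99.9), and germ line genes 3 of 16, bgcn (137), pum (96.0) and gcl (90.2). Heat shock genes had 4 of 14, led by Hsp27 (278), Hsp83 (170) and Hsp26 (128). No Hsp70 gene of the list was bound. The treatment of reads that map to several places, as in gene copies, is not given in the sources used here. The segment polarity list passed when a summit anywhere in the gene body counted (Fisher's exact test, adjusted p = 0.0153). Longer genes have more room for a summit under that rule, and lists were not matched on gene length. Lists of this size leave wide intervals, for example 7.57 to 47.6% for the gap and head gap list.

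Genes of the EGFR pathway and of the ecdysone response were bound at 5 of 12 (41.7%, 19.3 to 68.0%) and 5 of 13 members (38.5%, 17.7 to 64.5%). Neither list passed after adjustment (Fisher's exact test, adjusted p = 0.103 and 0.127). The EGFR ligand genes spi (204) and Krn (151) and the inhibitor gene aos (195) had the highest scores in the first. The ecdysone receptor gene EcR, with a score of 618 on 2R (6131809 to 6132340), and the nuclear receptor genes Hr3 (572) and Hr39 (316) led the second. The Hr3 summit was 217 bp from a TSS of Hr3 and from one of CG46321. Without replicate 3 or without replicate 4 the EGFR list passed (Fisher's exact test, adjusted p = 0.0200 and 0.0192). Both lists passed among the 1499 highest-scoring peaks, by nearest TSS and when a summit anywhere in the gene body counted. The gene body rule was not matched on gene length. Over all alternatives adjusted p ran from 0.00625 to 0.294 for EGFR and from 3.5e-04 to 0.928 for ecdysone genes (Fisher's exact or permutation tests). Against random lists matched on the number of TSSs, 4.03 bound ecdysone genes were expected, a ratio of 1.24 in place of 2.37 (permutation test, adjusted p = 0.928).

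**Figure D3:**
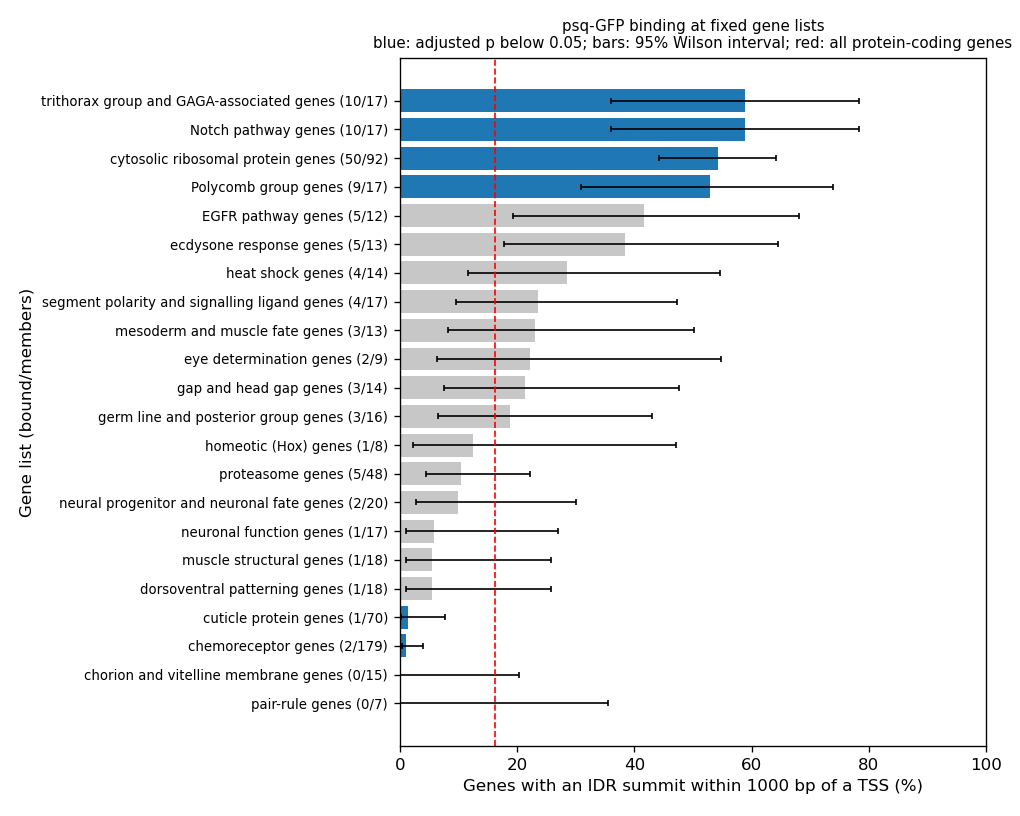
Share of each gene list with an IDR summit within 1000 bp of a TSS (x axis, %), with 95% Wilson intervals, bound and total members in the labels, and the 16.2% of all protein-coding genes as a red dashed line. Blue bars mark the 6 lists with an adjusted p below 0.05, 4 of them above the line and 2 near 0.

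GAGA repeats were more frequent at Psq-GFP summits than beside them. The GAGAG motif occurred within 100 bp of 33.1% of summits (31.4 to 34.8%) and in 23.6% of windows of equal width 1000 bp to the left (exact McNemar test, two-sided, adjusted p = 5.28e-16 over 11 motifs). The right flank had 23.8%. The longer GAGAGAG repeat occurred at 9.64% of summits and 4.17% of left flanks (exact McNemar test, adjusted p = 2.13e-16). Among the 500 strongest peaks it occurred at 14.4% of summits and 6.4% of left flanks. GAGAG was more frequent at summits both near promoters (29.2 against 21.3%) and elsewhere (38% against 26.5%), with adjusted p of 1.51e-07 and 2.74e-09 by the same test. It also exceeded the 22.2% of promoters of unbound genes, taken at matching offsets from the TSS (Fisher's exact test, adjusted p = 2.4e-05), an alternative chosen after seeing the data. With windows of 50 bp the excess over left flanks was 4.93 points for GAGAG and 1.73 points for GAGAGAG, in place of 9.50 and 5.47 points. With windows of 250 bp the excess of GAGAGAG was 12.8 points.

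DRE and Motif 1, elements of housekeeping core promoters, and the BEAF-32 core were also more frequent at summits. The BEAF-32 core, CGATA, is part of the DRE pattern, TATCGATA. Each window with DRE therefore also counted for BEAF-32, and their results are not independent. The DRE element was found at 3.10% of summits and 0.467% of left flanks, Motif 1 of the protein M1BP at 1.67 and 0.300%, and the BEAF-32 core at 28.9 and 21.5% (exact McNemar tests, adjusted p of 4.83e-15, 8.27e-08 and 1.09e-10). The excess of DRE was 1.43 points with windows of 50 bp and 5.37 points with 250 bp, in place of 2.63 points, and that of Motif 1 was 0.567 and 3.07 points, in place of 1.37 points. The right flank, which was not tested, had DRE in 1.13% of windows, Motif 1 in 0.267% and the BEAF-32 core in 20.7%. They passed at promoter peaks, while at other peaks the summit share was at or below that of the left flank, with adjusted p from 0.712 to 1. The difference between promoter and other peaks was not tested. Among the 500 strongest peaks none of these 3 motifs passed, with the BEAF-32 core at 25.4% of summits and 23.4% of left flanks (exact McNemar tests, adjusted p of 0.620 for BEAF-32 and 0.120 for DRE and Motif 1). Against promoters of unbound genes, DRE stayed more frequent (5.26 against 3.53%, Fisher's exact test, adjusted p = 0.0328), while Motif 1 (adjusted p = 0.398) and the BEAF-32 core (adjusted p = 0.0753) did not pass. In simulated peak sets with 60% of summits placed at random promoters, these 3 motifs were called in 97 to 100 of 100 draws, so the comparison with flanks also reads promoter composition.

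A tracts were found at 24.6% of summits against 16.1% of left flanks (exact McNemar test, adjusted p = 4.08e-16), and CA repeats at 11.3 against 8.5% (adjusted p = 4.4e-04 by the same test). CA repeats did not pass with windows of 50 bp (exact McNemar test, adjusted p = 0.191) or against unbound promoters (Fisher's exact test, adjusted p = 0.108). Their excess of 2.80 points was 9.60 points with windows of 250 bp (exact McNemar test, adjusted p = 1.4e-18). They passed at peaks away from promoters (14.8 against 9.57%, exact McNemar test, adjusted p = 1.6e-04) and did not pass at promoter peaks (8.49 against 7.66%, adjusted p = 0.437) or among the 500 strongest peaks (adjusted p = 0.120). The core motif of the Polycomb recruiter Pho was less frequent at summits, at 25.4 against 33.4% (exact McNemar test, adjusted p = 2.02e-11). In the simulated sets with promoter summits, A tracts were called in 62 and the Pho core in 49 of 100 draws, with mean differences of 2.32 and -2.61 points against the observed 8.503 and -8.00 points. Those promoter summits lay evenly on both sides of a TSS, while 74.7% of the observed ones lay upstream. The other simulated summits were placed at random, coding exons included. The simulated differences therefore need not hold all that position alone would give. A tracts and the Pho core both passed against unbound promoters, at 22.4 against 18.0% and 24.9 against 31.0% (Fisher's exact test, adjusted p of 0.00525 and 4.2e-04). Bound promoter windows had a mean GC content of 37.8% and unbound ones of 40.5%. This background was therefore not matched on base composition, and an effect of composition on these 2 motifs was not tested. Among the 500 strongest peaks A tracts passed (exact McNemar test, adjusted p = 0.0201) and the Pho core did not (adjusted p = 0.192). With windows of 50 bp the differences were 3.20 points for A tracts and -5.002 points for the Pho core. The Zelda motif (0.834 against 1.37%), the Zeste core (17.5 against 17.4%) and the E-box (10.4 against 9.37%) did not pass, with adjusted p of 0.0782, 0.890 and 0.231. The Zelda motif passed as less frequent with flanks at 2000 bp (adjusted p = 0.0470), without replicate 3 (0.0272), among the 1499 highest-scoring peaks (0.0429) and against unbound promoters (0.0328), by exact tests. Without replicate 4 the Zelda motif did not pass, with a difference of -0.300 in place of -0.534 points (exact McNemar test, adjusted p = 0.401). Its adjusted p over these and the other alternatives ran from 0.0272 to 0.486. By peak class it was less frequent at promoter summits (0.478 against 1.67%, exact McNemar test, adjusted p = 0.00164) and did not pass at other summits (1.28 against 0.980%, adjusted p = 0.804). The Zeste core and the E-box passed as more frequent with windows of 250 bp (exact McNemar test, adjusted p of 0.0193 and 7.0e-04). The E-box difference of 1.00 points was 0.400 points without replicate 4 and 1.33 points without replicate 3. Summit windows had a mean GC content of 38.4% and left flanks of 42.7%.

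**Figure D4:**
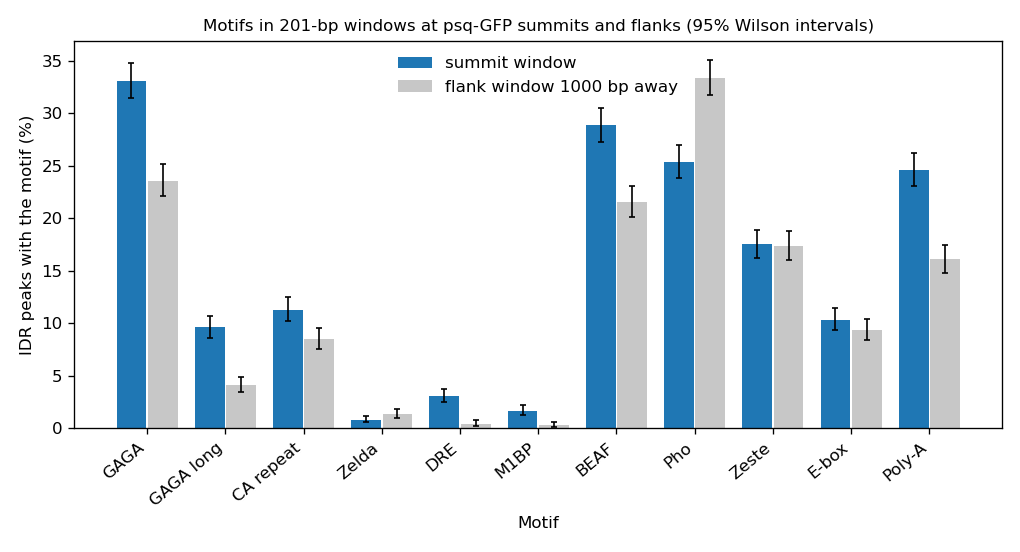
Share of IDR peaks (y axis, %) with each of 11 motifs within 100 bp of the summit (blue) and in the flank window 1000 bp to the left (grey), with 95% Wilson intervals. GAGAG is at 33.1% of summits and 23.6% of flanks, and the Pho core at 25.4 and 33.4%.

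Peaks with a GAGAG motif scored somewhat higher. Their median pooled score was 116 against 106 for peaks without it, a difference of 9.31 (permutation test with 100000 resamples, two-sided, adjusted p = 1.2e-04 over 6 tests). The difference was 4.99 in the scores of replicate 3 and 7.08 in those of replicate 4, each on that list's own scale, with adjusted p of 4.0e-04 and 2e-05 by the same test, the second from the smallest p that 100000 resamples can give. Promoter peaks had a median pooled score of 113 against 102 for other peaks, a difference of 11.0 (permutation test, adjusted p = 2e-05). With a TSS window of 250 bp the pooled promoter difference was 5.25 (permutation p = 0.0171). In replicate 4 the promoter difference of 4.93 (adjusted p = 1.3e-04) was 1.51 with a TSS window of 250 bp and did not pass (permutation p = 0.260). Among the 1499 highest-scoring peaks it did not pass in the scores of replicate 3 (permutation p = 0.0582) or replicate 4 (permutation p = 0.115). Among the 600 peaks with the highest scores, 39.7% had GAGAG (35.8 to 43.6%) and 64.5% were at promoters. In the 599 with the lowest scores these shares were 27.4% (24.0 to 31.1%) and 51.1%. Peaks are not replicates, so these p-values describe this peak set.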

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

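The tests of the ribosomal protein genes and of psq below were chosen after the result was seen, while those of the coding exons were written before their values were computed.

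The values of this paragraph come from peaks that the comparisons of the report do not use, and the control experiment was not analysed here. Below the IDR set, the pooled list placed 464 weaker peaks on chromosome 4, where its length would give 272, a ratio of 1.71 (exact binomial test, adjusted p = 1.11e-25). This is the opposite direction to the IDR set, in which chromosome 4 had 9 peaks at 0.298 of expectation. The weaker peaks of each replicate list had the same direction, with ratios of 1.52 in replicate 3 and 1.86 in replicate 4. Among the weaker pooled peaks every other arm passed the same test too, with ratios from 0.908 on 2R to 1.10 on 2L. A pass alone therefore does not set chromosome 4 apart, though it had the largest ratio. Peaks also cluster, while this test takes them as independent draws, so its p-values can be too small. In dm3, 119 pooled peaks lay outside the main arms, all of them outside the IDR set, including 38 on 3LHet, 31 on 3RHet and 30 on 2RHet. In dm6, 687 pooled peaks had the best q of the list but scores under the IDR set.

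Coding exons away from promoters held 7 of the 2999 IDR summits, or 0.233%, with an upper 95% bound of 0.481%. GC content was weighed first, because coding exons are rich in GC and summit windows are not. Shifted positions drawn to the GC make-up of the summit windows still lay in coding exons in 8.27% of cases (95% range over 100 shifts 7.27 to 9.14%), which argues against GC content as the whole cause. Positions at the same signed distance from another TSS gave 11.1% (10.1 to 12.2%), which argues against distance from TSSs. In the pooled list the share rose with falling rank, from 0.467% at ranks 3000 to 5998 to 8.16% at ranks 14996 to 30000, and no biological explanation was tested.

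Ribosomal protein genes were bound at 50 of 92 members. Random lists with the same numbers of TSSs held 17.9 bound members on average and gave a two-sided p of 0.0002, the smallest that 10000 lists can give, which argues against the number of TSSs. Counting only genes with the nearest TSS to a summit left 47.8% bound, which argues against peaks of neighbouring promoters. Proteasome genes were bound at 10.4% (upper bound 22.2%), and by nearest TSS at 2.08%. That upper bound lies below the lower bound of 44.2% for ribosomal protein genes. This argues against an equal pull-down of ribosomal protein and proteasome genes. It cannot decide on housekeeping promoters at large, because use of each proteasome gene in all cells was not checked. A pull-down that grows with transcription stays open, since no expression values were analysed here, and no biological explanation was tested.

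The psq gene held 19 IDR summits, and the tagged line may carry extra copies of psq DNA, which would raise reads along the copied stretch. Such copies would also add weaker peaks, a comparison whose bounds were set after the count was known. The pooled list had 31 weaker peaks over psq, and 9 other windows of the same length with at least 10 IDR summits had between 16 and 44, with a median of 31. Extra copies and dense binding cannot be told apart here, because the ends of the transgene are not stated in the labels and the control reads were not analysed here.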

How the results depend on the processing

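The 6 called lists, the promoter share and the GAGAG excess kept their direction and their side of the threshold in every alternative run for them, with promoter shares 2.84 to 5.92 times those of shifted summits and GAGAG excesses of 4.93 to 13.5 points. Of 189 alternative values for the main results, 170 did so, moved by less than their interval or, for counts, stayed within a factor of 1.5. None reversed, and all 46 that left out a replicate were among the 170. The count rule is loose: 2271 against 2999 peaks and 9 against 6 called lists were taken as unchanged. The promoter share entered both as a share and as a fold over shifts. Alternatives with unbound promoters, gene exposure and the nearest TSS were chosen after seeing the data. Depth is unknown, so its limit could not be set. The arm test in dm3 was not run, because no dm3 lengths were used here. No pairing of samples between conditions was possible because there is 1 group. The motif tests against flanks paired each summit window with the left flank of the same peak.

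The replicate correlation was 0.682 with summits within 100 bp, 0.626 with 50% reciprocal overlap and 0.765 in the 1499 highest-scoring peaks. The share of IDR peaks among the strongest of replicate 3 was 82.0, 78.3 and 99.7% under these settings, and of replicate 4 83.6, 78.8 and 99.7%. Among the 1499 peaks 0 arms passed, with chromosome 4 at 0.397 of expectation, and with gene exposure it was at 0.523. CA repeats exceeded flanks by 0.867 points with 50 bp windows. Over unbound promoters the excess was 1.67 points for CA repeats, 0.598 for Motif 1 and 3.29 for the BEAF-32 core, none past the threshold. The promoter score difference was 4.51 for replicate 3 and 5.31 for replicate 4 among the 1499 peaks, and 1.51 for replicate 4 with the 250 bp TSS window. The cause was not tested.

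Direction turned in 21 values for uncalled results, none past the threshold. Against gene exposure, arms 2L, 2R and X were at 0.922, 0.964 and 1.07 of expectation. Among the 1499 peaks, arms 3L and 3R were at 0.991 and 1.03 and the Zeste difference was -0.734 points. The ratios of list to other genes there were 0 for gap, 0.650 for segment polarity, 1.11 for neural fate, 0.850 for mesoderm and 0.690 for germ line genes. The germ line ratio was 0.849 with 1 TSS per gene and 0.954 against matched lists. The eye gene ratio was 0.788 with the 500 bp window. The homeotic ratio was 1.08 by nearest TSS and 1.37 with the gene body, where neural fate genes also had 1.37. With 50 bp windows Zeste was at -1.0 and the E-box at -0.233 points. Leaving out a replicate gave Zeste differences from -0.233 to 0.100 and mesoderm ratios from 0.971 to 1.45. Another 17 uncalled values passed the threshold, among them the EGFR ratio at 3.14 and 3.16 from single replicates. Of 67 named pairs of gene and peak, in which the Hel89B peak also counts for mor, 65 were among the 2999 strongest of each replicate. They had been named for high pooled scores, which come from both replicates, so this was partly built in.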

Other observations

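The tests in this part were chosen after the data were seen. Windows as long as the psq gene were ranked by IDR summits, and the densest after the lola and psq region, with 19 summits, held Psc and its neighbours on 2R with 15 (12947675 to 13007067). Next came the window of tara on 3R with 14 (16214290 to 16273682) and that of CG43736 and CG14434 on X with 14. Tlk and Smr on X each marked a window with 12, ush and cbt on 2L a window with 11, and 3 windows held 10, those of tou and atos on 2R, PAN3 and CG2162 on 3L, and InR on 3R. Psc encodes a Polycomb protein, Smr a nuclear receptor corepressor and InR the insulin receptor.

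Among other gene classes, snoRNA genes had a summit within 1000 bp of a TSS in 36 of 269 cases (13.4%), non-coding RNA genes in 254 of 3261 (7.79%) and tRNA genes in 16 of 290 (5.52%). No rRNA gene of 99 and no snRNA gene of 32 was bound, which allows up to 3.74 and 10.7%. Genes with near-identical copies are uncertain here, since the treatment of reads that map to several places is not given in the sources used here.

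All 2080 6-mers, counted with their reverse complements, were ranked on arms 2L, 3L and 4, and the 20 at the ends of the ranking were tested on 2R, 3R and X. Of the 10 most enriched, 9 held only A and T. The exception was ACACTG, found at 16.3% of 1808 test summits (14.7 to 18.1%) and 8.57% of left flanks (exact McNemar test, adjusted p = 6.26e-12). It was more frequent at promoter summits (17.7 against 9.37%) and at other summits (14.5 against 7.58%). At the other end CCAGGA occurred at 0.940% of test summits and 9.40% of left flanks (exact McNemar test, adjusted p = 4.15e-32). At summits away from promoters these shares were 0.994 and 6.46%. Over all IDR peaks, summit windows had a mean GC content of 38.4% and left flanks of 42.7%. Coding exons away from promoters held 0.233% of IDR summits against 13.8% of shifted ones. The flanks were matched for neither, and an effect of base composition or coding sequence on these 6-mers was not tested.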
